A study of Mus musculus with 10 samples.

How the data were processed

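RNA from 10 cultures of J558 cells was measured on Affymetrix whole-transcript gene arrays: 3 with empty vector, 3 with wild-type Pax5 and 4 with Pax5 G183S. Per the labels' protocols, the retroviral vector also carried puromycin resistance and green fluorescent protein; cells were kept in puromycin for 5 to 7 days and then sorted for green fluorescence and IgM, RNA was extracted with Trizol, and 100 ng of total RNA was amplified with the Ambion WT Expression Kit. The sort can affect which cells are measured in every group. Groups and replicate numbers were taken from the sample labels, which call the replicates independent and biological.

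The deposited values are log2 expression per probe set. RMA, which corrects background, normalizes between arrays and summarises probes, and Partek are named in the submitters' processing notes without versions or roles; which arrays were normalized together and any filter are not given in the sources used here. RMA forces arrays to a common distribution, so a shift shared by most genes would not be visible. Scanner files, detection calls and scan dates were not used here, so no level could be called absent and no scan batch could be tested. No filter was applied to dim probe sets in the main comparisons.

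The table held 34760 probe sets. The platform annotation listed 22961 of them, 21640 with 1 gene symbol and 1321 with several; 11799 had no entry and are unnamed here. Symbols were checked through gene identifiers against the RefSeq gene table of GRCm38.p6, used for names only; 21553 of the single-symbol probe sets matched and 0 symbols changed. Where a gene had more than 1 probe set (954 genes), the one with the highest mean over all arrays was used, which left 19937 genes. No genome build is named for the arrays, so no coordinates are given. Probe sets of 1 gene can differ: among the named genes, for Ywhaz, Ighm, Igha, Pdia4, Idi1 and Bnip3, none of them called, a probe set not used differed in direction in at least 1 comparison.

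Comparisons used limma 3.58.1 in R 4.3.3, with 1 coefficient per group, all 10 arrays in 1 fit, empirical Bayes moderation (7 residual and 2.88 prior degrees of freedom) and Benjamini-Hochberg adjustment over the 19937 genes; genes with two-sided adjusted p under 0.05 were called. Log2 fold changes are given with limma's standard error. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.

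The design, the 21 gene lists, the rule for naming genes and the alternative settings, apart from those named as added, were fixed before the data were examined. Lists cover Pax5-activated and Pax5-repressed genes from earlier work, B-cell receptor signalling, mature B-cell, plasma-cell, pro-B and pre-B, MHC class II, immunoglobulin constant, endoplasmic reticulum stress, cell-cycle, p53 response, interferon, NF-kB, immediate early, cholesterol, glycolysis and reference genes, and T-cell, myeloid, erythroid and stromal markers. Of 391 list genes, 45 were not among the single-symbol probe sets; the immunoglobulin list kept 4 members and the erythroid list 7. Lists overlap: the Pax5-activated list shares 7 genes with B-cell receptor signalling and 7 with the mature B-cell list, and the Pax5-repressed list 7 with the plasma-cell list. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 21 lists within a comparison; an estimated correlation and fry were alternatives. With the estimated correlation no list passed in any comparison.

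Named genes are Pax5, the up to 12 with the largest increase and the 12 with the largest decrease among called genes whose groups do not overlap, leaving out predicted, clone-named, receptor-family, small-RNA and antigen-receptor segment symbols (19 called genes with wild type, 3 with G183S), up to 4 members of each list with the smallest adjusted p, and Cd79a, Cd79b, Blnk, Prdm1, Xbp1, Irf4, Ighm and Igha; a further gene of the rule is not reported.

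The response to G183S relative to wild type was estimated on genes with adjusted p under 0.05 and at least 1 log2 unit of change in a fit without 1 wild-type and 1 empty-vector array. It is the median G183S response against the held-out empty-vector array over the median response of the held-out wild-type array, averaged over the 9 combinations. A combination needed at least 5 genes, a minimum set during the analysis and not in the design; only 4 combinations for rising and 2 for falling genes met it, and with no minimum the ratios were 0.674 over 9 and 1.28 over 6 combinations. Shared controls were simulated 50 times, list scores were compared by an exact permutation test, and the groups were also compared under all other splits of the same arrays.

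The fits were tested on simulated arrays with the real means and spreads and 200 of 19937 genes changed, 20 simulations per comparison. Changes of 1 log2 unit were recovered in 87.6% of cases for wild type against empty vector, 90.4% for G183S against empty vector and 89.0% for G183S against wild type, and changes of 2 log2 units in 98.5%, 98.5% and 98.3%. False calls made up 5.05%, 4.84% and 5.24% of calls. Noise was drawn independently for every gene and array, without correlation between genes or the structure among arrays seen here. These shares therefore do not give the power or the rate of false calls in the real data. In 5 further simulations a true response ratio of 0.6 was estimated as 0.601 for rising and 0.599 for falling genes. Genes chosen without holding arrays out gave 0.601 and 0.600. These simulations therefore could not show the bias that holding arrays out is meant to avoid. They also held larger changes in more genes than the real selections. In a single simulated data set 0 of 20 unmoved lists were called, but its genes were independent, so the preset correlation was not tested.

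Alternatives were a filter on dim probe sets, quantile normalization of the values again, median centring, a fit of the groups compared alone, trended and robust moderation, no moderation, array weights, the mean of a gene's probe sets, all probe sets, the replicate number as a block, a fold minimum, each array left out in turn, and for the ratio other selections and a regression slope. Added after the data were seen were fits without G183S replicate 1 and wild-type replicate 3 together, selection of genes on all Pax5 arrays, and the ratio with no minimum number of genes.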

Results

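Gene expression was measured on Affymetrix whole-transcript arrays in J558 cells, a mouse myeloma line of plasma-cell type. The cells had been transduced with a retroviral vector carrying no insert, wild-type Pax5 or Pax5 G183S. Pax5 is the transcription factor that commits cells to the B lineage and is shut off in plasma cells; G183S replaces a glycine by serine in its octapeptide motif. The series title concerns inherited PAX5 changes and leukaemia risk, and the comparisons ask what each construct changed and whether the mutant and wild-type proteins acted alike. There were 3 empty-vector, 3 wild-type and 4 G183S arrays, described by the labels as independent replicates. Array medians over all probe sets lay between 6.81 and 6.94 log2 units. Pearson correlations across genes were 0.985 to 0.998 within groups and 0.978 to 0.995 between groups, with no identical pair. The highest value between groups was that of wild-type replicate 2 and G183S replicate 1, and the lowest within a group was that of G183S replicates 1 and 3. On the first principal component, which held 42.2% of the variance, G183S replicate 1 scored 24.8 and the other G183S arrays -8.75, -21.6 and -12.6, while the wild-type arrays scored 39.6, 17.5 and 2.12. The number of arrays limits the precision of every value.

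**Figure D1:**
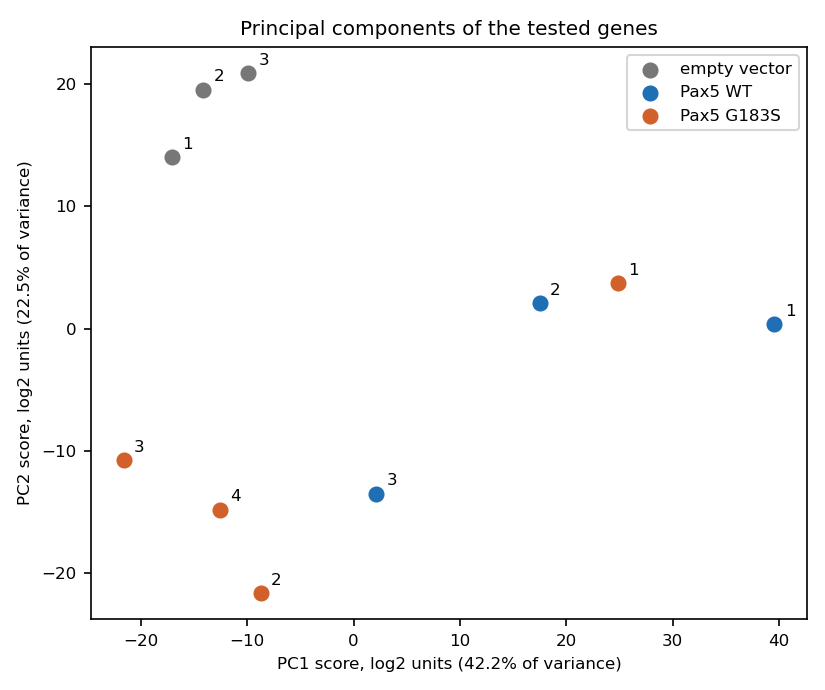
Scores of the 10 arrays on the first (x axis, 42.2% of variance) and second (y axis, 22.5% of variance) principal components, in log2 units; each point is 1 array, coloured by group and numbered by replicate. G183S replicate 1 lies at 24.8 on the first component, between wild-type replicates 1 (39.6) and 2 (17.5).

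Pax5 transcript was high in every array of cells given a Pax5 vector. Its probe set (10512669) read 7.10, 6.84 and 7.01 log2 units in the empty-vector arrays, 10.67, 10.09 and 10.05 in the wild-type arrays, and 10.22, 10.36, 9.38 and 9.96 in the G183S arrays. Pax5 was higher with wild type than with empty vector (log2 fold change 3.29 ± 0.24 SE, limma adjusted p = 0.00109) and higher with G183S (means 9.98 ± 0.43 and 6.98 ± 0.13 SD, limma adjusted p = 0.00117). Between G183S and wild type the log2 difference was -0.29 ± 0.23 SE, which did not pass (limma adjusted p = 0.674). The probe set gives 1 value per array, so it tells cells with a Pax5 vector from those with empty vector but not mutant from wild-type transcript.

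**Figure D2:**
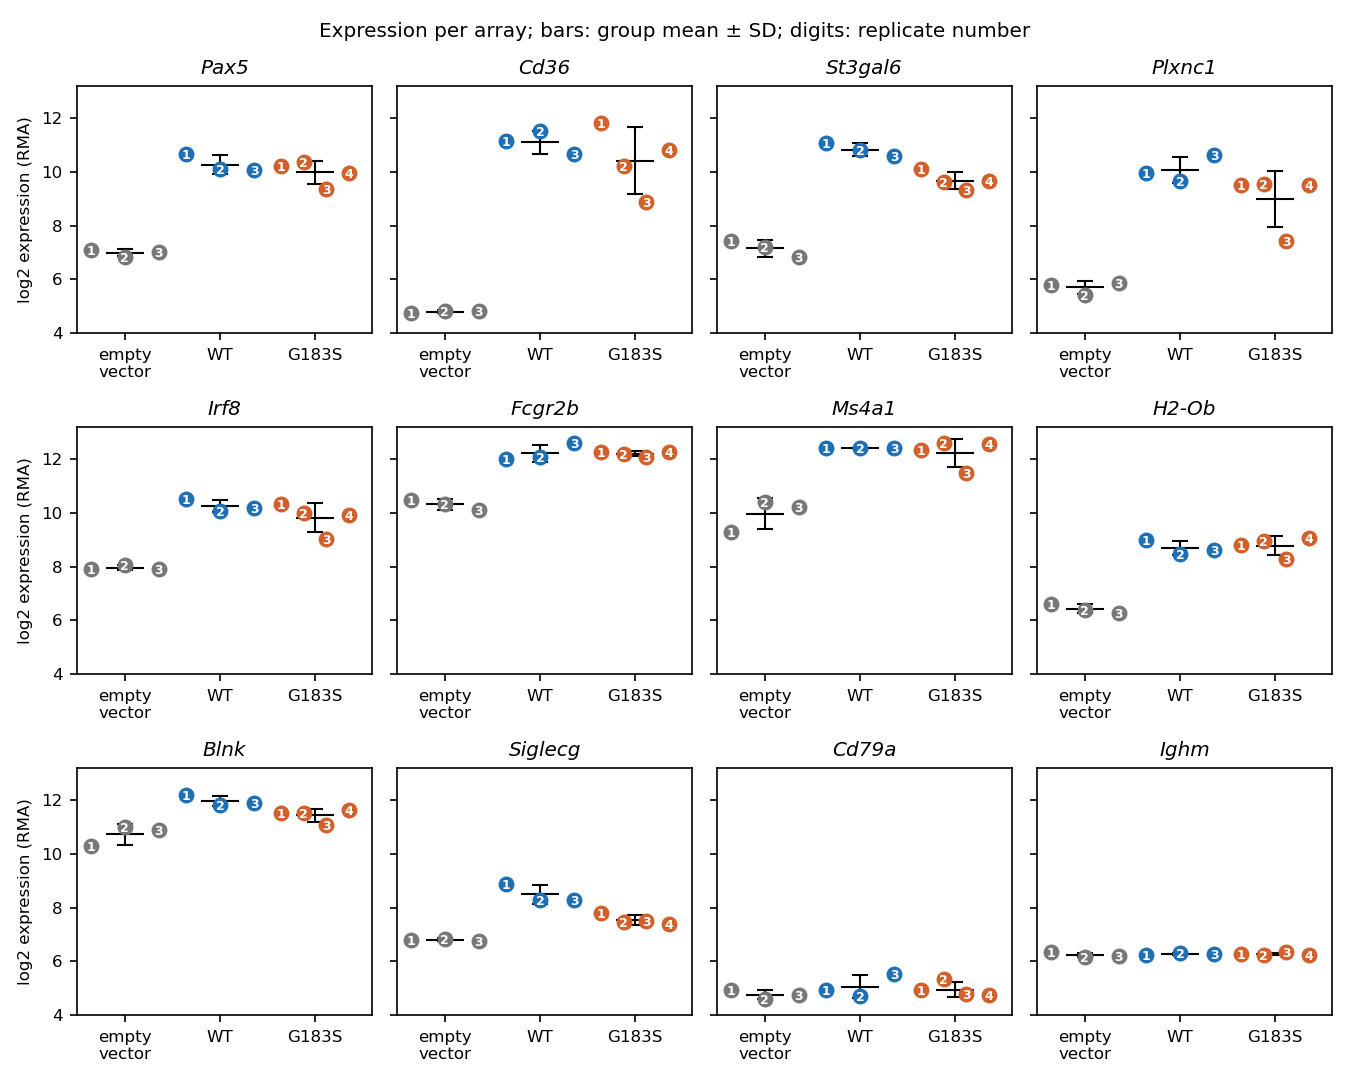
Log2 expression (y axis) of 12 genes in the 10 arrays by group (x axis); each point is 1 array with its replicate number, and black marks give the group mean ± SD. Pax5, Cd36, St3gal6, Plxnc1, Irf8, Fcgr2b, Ms4a1 and H2-Ob are higher in every Pax5 array than in any empty-vector array, while Cd79a and Ighm stay at similar low values in all groups.

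Wild-type Pax5 raised genes of several functions and lowered others. Cd36, a scavenger receptor for lipids, had the largest increase, from 4.79 ± 0.05 to 11.10 ± 0.43 log2 units (SD, n = 3 each). The log2 difference was 6.31 ± 0.58 SE (limma adjusted p = 0.00324). St3gal6, a sialyltransferase, rose by 3.68 ± 0.21 log2 units (adjusted p = 1.85e-04), the semaphorin receptor Plxnc1 by 4.39 ± 0.51 log2 units (adjusted p = 0.00767) and H2-Ea, the alpha chain of an MHC class II molecule, by 3.96 ± 0.68 (adjusted p = 0.0248). With empty vector these 4 genes read below 7.23 log2 units, the level under which a probe set was treated as dim. Background signal was not used here, so how far it limits the size of their log2 changes is not known. The formin Fhod3 (3.36), the membrane-shaping protein Bin1 (2.75), the IgE receptor gene Fcer2a (2.74) and the aryl hydrocarbon receptor gene Ahr (2.48, all log2 fold changes) rose as well. Genes that fell had smaller changes, led by Sez6l2 (-1.85), the Groucho-family gene Tle6 (-1.80), the lipid transporter gene Abcg1 (-1.61), the retinal reductase gene Dhrs3 (-1.58), the glucocorticoid-induced gene Tsc22d3 (-1.56) and the adhesion molecule gene Pecam1 (-1.54).

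In all, 374 of 19937 genes passed limma's adjusted p of 0.05 between wild type and empty vector, 176 higher and 198 lower, and 107 of these changed by at least 1 log2 unit (71 higher, 36 lower). The higher genes include Pax5 itself, the gene introduced, which is left out of the 40 named genes below. In each of the 374, every array of one group lay beyond every array of the other. Over all genes 4791 (24.0%) did so, against 10% by chance, and 3175 genes (15.9%) had an unadjusted p under 0.05. With each array centred on its median the split was 100 higher and 218 lower. Higher calls outnumbered lower ones without empty-vector replicates 1 (67 and 55), 2 (13 and 8) or 3 (6 and 0) or wild-type replicate 1 (50 and 40). The count fell to 122, 21 and 6 without empty-vector replicates 1, 2 and 3, to 90 and 186 without wild-type replicates 1 and 2, and to 212 and 214 without G183S replicates 2 and 4, which share the estimate of spread. It was 1033 without G183S replicate 1. Of 40 named genes past the threshold, Cd36, St3gal6, Fcgr2b, H2-Ob and Siglecg passed it whichever array was left out; 19, 10 and 5 passed without empty-vector replicates 1, 2 and 3, 19, 19 and 33 without wild-type replicates 1, 2 and 3, and 40, 26, 37 and 26 without G183S replicates 1 to 4.

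MHC class II genes, which present antigen on B cells, were higher with wild-type Pax5. Of 11 measured members 5 rose, among them H2-Ob (2.27), H2-Eb2 (2.33), H2-Eb1 (1.73) and the invariant chain gene Cd74 (log2 fold change 0.93, adjusted p = 0.0308), and H2-Ab1 (1.54, chosen after its value was seen); 8 passed when adjusted over the list alone. As a list they lay above other genes (camera adjusted p = 2.34e-07; adjusted p = 0.123 with an estimated correlation). Mature B-cell genes were shifted upward as a list, with 3 of 29 higher (Ms4a1, which encodes CD20, 2.43; Fcer2a 2.74; Cd24a 1.14) and 8 adjusted over the list alone (camera adjusted p = 7.45e-06; adjusted p = 0.104 with an estimated correlation). Among 27 genes described earlier as activated by Pax5, 4 rose, namely the transcription factor gene Irf8 (2.29), Siglecg, an inhibitory receptor gene of B cells (1.69), the B-cell receptor adaptor gene Blnk (1.25) and Fcer2a, while Prkd2 fell (-0.76, chosen after its value was seen). Adjusted over the list alone, 9 were higher and 2 lower (camera adjusted p = 2.67e-04; adjusted p = 0.104 with an estimated correlation). B-cell receptor signalling genes had 4 of 27 higher, the inhibitory Fc receptor gene Fcgr2b (1.91), Siglecg, Blnk and the kinase gene Tec (0.60), and 6 adjusted over the list alone (camera adjusted p = 0.00125; adjusted p = 0.104 with an estimated correlation). These 4 lists also passed limma's directional fry test (adjusted p = 0.00528 each).

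Cell-cycle genes were shifted upward with wild-type Pax5, although only the kinetochore gene Cenpf (1.52) of 25 passed by itself, also when adjusted over the list alone (camera adjusted p = 3.47e-05; adjusted p = 0.613 with an estimated correlation). Empty-vector replicate 1 stood apart (-0.30 from the group mean, the others 0.14 and 0.15); without it the list mean differed by 0.26 in place of 0.41 (camera adjusted p = 0.0314). Interferon-stimulated genes were shifted downward with 0 of 20 past limma's threshold, also when adjusted over the list alone; Xaf1 (-1.18, adjusted p = 0.117) and Mx1 (-0.60, adjusted p = 0.143) are examples (camera adjusted p = 0.0172; adjusted p = 0.485 with an estimated correlation). That call was lost without empty-vector replicate 2 (adjusted p = 0.0671) or wild-type replicate 1 (adjusted p = 0.108), where the list mean differed by -0.14 in place of -0.27, and with dim probe sets left out (adjusted p = 0.243). The other 15 lists did not pass camera. Their camera adjusted p was 0.0510 for p53 response, 0.344 for immediate early genes and stromal markers, 0.403 for plasma-cell, pro-B and pre-B, endoplasmic reticulum stress and glycolysis genes, 0.492 for Pax5-repressed, immunoglobulin constant, NF-kB target, T-cell marker and erythroid marker genes, 0.697 for reference genes, 0.791 for myeloid markers and 0.920 for cholesterol synthesis. Median, mean and test differed in sign for the Pax5-repressed, NF-kB, reference and T-cell lists. Single members past the threshold there were Rrm2b (1.12), Rel (0.56), Egr1 (1.27), Jund (-0.37), Cd3g (-1.09) and Pecam1. In limma's mixed fry test, which asks for change in either direction, some of these lists did pass. They were Pax5-repressed (mixed fry adjusted p = 0.0250), immediate early (1.36e-04), T-cell marker (3.30e-06) and stromal marker genes (1.06e-05). The signalling chain gene Cd79a (0.30, adjusted p = 0.555), Cd79b (-0.43, adjusted p = 0.282), the plasma-cell factors Prdm1 (0.36, adjusted p = 0.580), Xbp1 (-0.23, adjusted p = 0.506) and Irf4 (0.58, adjusted p = 0.323), and the immunoglobulin genes Ighm (0.05, adjusted p = 0.803) and Igha (-0.31, adjusted p = 0.450) did not pass. Cd79a lay at 4.76, 5.05 and 4.95 log2 units in the empty-vector, wild-type and G183S means.

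With Pax5 G183S many of the same genes headed the list. Cd36 was higher than with empty vector (log2 fold change 5.63 ± 0.54 SE, limma adjusted p = 0.00311), from 4.79 ± 0.05 (SD, n = 3) to 10.42 ± 1.23 (n = 4) log2 units. St3gal6 rose by 2.52 ± 0.20 (adjusted p = 0.00117), Bin1 by 3.02 ± 0.27 (adjusted p = 0.00198), H2-Ob by 2.35 ± 0.19 (adjusted p = 0.00117) and Fcgr2b by 1.89 ± 0.14 log2 units (adjusted p = 0.00117). Plxnc1 (3.30), Ms4a1 (2.27), H2-Eb2 (2.24), Fhod3 (2.13), Irf8 (1.85) and Psd3 (1.56) were also higher. Lower genes included Pecam1 (-1.54), the monocarboxylate transporter family gene Slc16a5 (-1.54), the platelet glycoprotein gene Gp9 (-1.48, adjusted p = 0.00129), the tetraspanin gene Tspan14 (-1.33), the potassium channel gene Kcnn4 (-1.17), the T-cell receptor complex gene Cd3g (-1.15), the small GTPase gene Rhob (-1.14) and the fucosyltransferase gene Fut8 (-1.08). Plxnc1 read 7.43 in G183S replicate 3 and 9.50 to 9.54 in the other G183S arrays.

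Between G183S and empty vector 62 genes passed limma's threshold, 20 higher and 42 lower, of which 29 changed by at least 1 log2 unit (14 higher, 15 lower). All 62 had non-overlapping groups; over all genes 2308 (11.6%) did, against 5.71% by chance, and 2253 (11.3%) had an unadjusted p under 0.05. The higher genes again include Pax5, which is left out of the 24 named genes below. The excess of lower calls was not stable. Without empty-vector replicates 1, 2 and 3 there were 50 higher and 37 lower, 6 and 5, and 6 and 2. Without G183S replicates 1 and 3 there were 143 and 152, and 69 and 75. The count was 11 and 8 without empty-vector replicates 2 and 3, 112 without wild-type replicate 1, and 295, 22, 144 and 24 without G183S replicates 1, 2, 3 and 4. Of 24 named genes past the threshold, Cd36, St3gal6, Bin1, H2-Ob, Fcgr2b and Gp9 passed it whichever array was left out; 18, 7 and 6 passed without empty-vector replicates 1 to 3, 24, 20 and 21 without wild-type replicates 1 to 3, and 24, 11, 23 and 11 without G183S replicates 1 to 4.

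The B-lineage groups were again higher. MHC class II genes had 2 of 11 past the threshold, H2-Ob and H2-Eb2, and 7 adjusted over the list alone (camera adjusted p = 1.17e-09; adjusted p = 0.136 with an estimated correlation). Mature B-cell genes had 1 of 29, Ms4a1, and 5 adjusted over the list alone (camera adjusted p = 4.90e-05; adjusted p = 0.136 with an estimated correlation). Pax5-activated genes had 1 of 27, Irf8, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 8.95e-04; adjusted p = 0.153 with an estimated correlation). Siglecg (0.74, adjusted p = 0.0762), Blnk (0.70, adjusted p = 0.150) and Fcer2a (adjusted p = 0.0501) did not pass. B-cell receptor signalling genes had 1 of 27, Fcgr2b, and 4 adjusted over the list alone (camera adjusted p = 0.0285; adjusted p = 0.270 with an estimated correlation), a call lost without empty-vector replicate 1 (adjusted p = 0.0672), without G183S replicate 1 (adjusted p = 0.169) or with dim probe sets left out (adjusted p = 0.181). All 4 passed the directional fry test, with adjusted p = 0.0256 for MHC class II, 0.0375 for mature B-cell and 0.0420 for the other lists.

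Plasma-cell genes were shifted downward with G183S. None of 19 passed limma's threshold alone and 4 were lower adjusted over the list alone; Tnfrsf17, the plasma-cell survival receptor BCMA (-2.08, adjusted p = 0.119), and Sdc1, the plasma-cell surface marker CD138 (-1.14, adjusted p = 0.119), are examples (camera adjusted p = 2.36e-04; adjusted p = 0.442 with an estimated correlation). The mean of this list differed from the empty-vector mean by 0.10 in G183S replicate 1 and by -0.68, -0.53 and -0.43 in replicates 2, 3 and 4. NF-kB targets were shifted upward with 0 of 17 past the threshold and 3 adjusted over the list alone, such as Cd40 (1.11, adjusted p = 0.151) and Traf1 (0.95, adjusted p = 0.171; camera adjusted p = 4.47e-05; adjusted p = 0.442 with an estimated correlation). Their list mean differed from empty vector by -0.04 in G183S replicate 1 and by 0.52, 0.49 and 0.53 in the others. Glycolysis genes were shifted downward with 0 of 17 past the threshold and 1, Tpi1 (-0.51, adjusted p = 0.0754), adjusted over the list alone (camera adjusted p = 0.00203; adjusted p = 0.437 with an estimated correlation). The remaining 14 lists had camera adjusted p from 0.0680 (interferon) to 0.859 (reference genes), with 0.602 for the Pax5-repressed list, whose median and mean differed in sign. Cd3g, Pecam1 and Jund (-0.45, adjusted p = 0.0421) passed as single members of such lists. Mixed fry passed for immediate early (adjusted p = 1.08e-04), T-cell marker (5.47e-06) and stromal marker genes (0.0111), but not for Pax5-repressed genes (0.0999). Cd79a (0.19), Irf4 (-0.01), Prdm1 (-0.11), Xbp1 (-0.33), Ighm (0.03) and Igha (-0.39) did not pass.

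**Figure D3:**
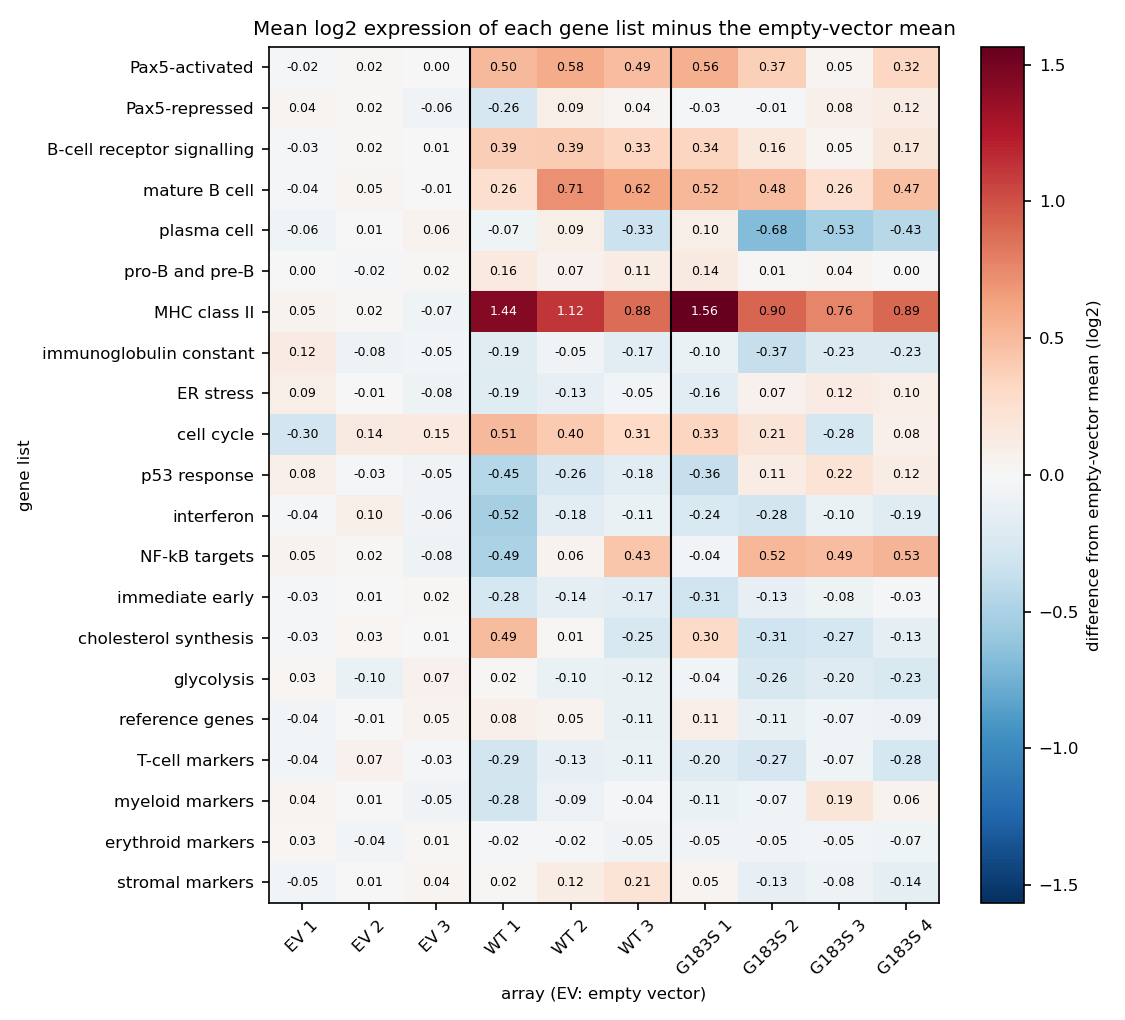
Mean log2 expression of the genes of each of the 21 lists (y axis) in each array (x axis) minus the empty-vector mean, in log2 units, as colour and number. MHC class II genes are 0.76 to 1.56 higher in all Pax5 arrays, whereas plasma-cell and NF-kB genes in G183S replicate 1 (0.10 and -0.04) lie apart from the other G183S arrays.

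Direct comparison of G183S with wild type found no single gene past the threshold. Among genes named by rule the smallest adjusted p was that of Siglecg, at 7.39 to 7.81 log2 units in the G183S arrays against 8.88, 8.29 and 8.30 in the wild-type arrays (log2 difference -0.95 ± 0.15 SE, limma adjusted p = 0.263), and the co-stimulatory molecule gene Cd86 (-0.61 ± 0.10, adjusted p = 0.263). Nt5c2 (-1.30) and Nckap1 (1.56), chosen for their p after the values were seen, had the same adjusted p of 0.263. St3gal6 differed by -1.16 (adjusted p = 0.279), Blnk by -0.55 (adjusted p = 0.499), Cd36 by -0.68 (adjusted p = 0.681) and Fcgr2b by -0.02 (adjusted p = 0.964). limma called 0 genes, although 1891 (9.48%) had an unadjusted p under 0.05 and 1295 (6.5%) had non-overlapping groups, against 5.71% by chance; a linear model without moderation called 1. With array weights, which gave G183S replicate 1 a low weight of 0.335, limma called 2752 (1655 higher, 1097 lower). The count was 1113 without G183S replicate 1 (811 higher, 302 lower), 3 without wild-type replicate 1, 1 without empty-vector replicate 1 and 0 without any other array.

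Several groups nevertheless passed as lists between G183S and wild type with camera at the preset correlation, though not with an estimated one. Each had 0 members past limma's threshold. Cell-cycle genes were lower, Cenpf for instance by a log2 difference of -1.11 (adjusted p = 0.484), with 0 adjusted over the list alone (camera adjusted p = 0.00101; adjusted p = 0.646 with an estimated correlation). Relative to empty vector their list mean was 0.51, 0.40 and 0.31 in the wild-type arrays and 0.33, 0.21, -0.28 and 0.08 in the G183S arrays. Without G183S replicate 3 the difference was -0.20 in place of -0.32 (camera adjusted p = 0.0354). NF-kB targets were higher, such as the adhesion molecule gene Icam1 (1.22, adjusted p = 0.508), with 0 adjusted over the list alone (camera adjusted p = 0.00188; adjusted p = 0.646 with an estimated correlation). Genes of the p53 response were higher, with 5 adjusted over the list alone, among them Zmat3 (1.09, adjusted p = 0.395), Ei24 (0.67, adjusted p = 0.395) and Ccng1 (0.92, adjusted p = 0.484; camera adjusted p = 0.00925; adjusted p = 0.646 with an estimated correlation). Their list mean relative to empty vector was -0.45, -0.26 and -0.18 in the wild-type arrays, -0.36 in G183S replicate 1 and 0.11, 0.22 and 0.12 in G183S replicates 2 to 4. Plasma-cell genes were lower, as in Tnfrsf17 (-1.30, adjusted p = 0.508), with 0 adjusted over the list alone (camera adjusted p = 0.0127; adjusted p = 0.672 with an estimated correlation). Endoplasmic reticulum stress genes were higher and B-cell receptor and stromal marker genes lower (camera adjusted p = 0.0494 each; adjusted p = 0.646 each with an estimated correlation), with 0, 1 and 0 members adjusted over the list alone.

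Some of these list calls rested on single arrays or on a processing choice. The NF-kB call was lost without wild-type replicate 1 (adjusted p = 0.356), where the list mean differed by 0.13 in place of 0.37. Without wild-type replicate 3 it differed by 0.59. The plasma-cell call was lost without wild-type replicate 2 (0.168) or G183S replicates 2 (0.132) or 3 (0.0771, all adjusted p). The list mean differed by -0.28, and by -0.18 without wild-type replicate 2 or G183S replicate 2 and -0.44 without G183S replicate 1. The stress call was lost without empty-vector replicate 2 (0.0546), wild-type replicates 2 (0.128) or 3 (0.162), or G183S replicates 2 (0.0963), 3 (0.102) or 4 (0.0780), and with dim probe sets left out (0.160). The B-cell receptor call was lost without any empty-vector array (0.0545, 0.0546 and 0.0562), wild-type replicates 2 (0.0637) or 3 (0.162), or G183S replicates 2 (0.0963) or 3 (0.150), with median centring (0.0716) and in a fit of the 2 groups alone (0.0622). The stromal call was lost without any empty-vector array (0.0589, 0.0546 and 0.0562), wild-type replicates 2 (0.0637) or 3 (0.401), or G183S replicates 1 (0.0518), 2 (0.132) or 4 (0.139), and in a fit of the 2 groups alone (0.0622). No list passed the directional fry test and Pax5-activated genes alone passed its mixed form, which asks for change in either direction (adjusted p = 0.0180). The other 14 lists had camera adjusted p from 0.0747 (glycolysis) to 0.975 (erythroid markers), with 0.719 for MHC class II and 0.171 for Pax5-activated genes; median, mean and test differed in sign for immediate early, reference and erythroid genes. Prdm1 (-0.47), Irf4 (-0.58), Xbp1 (-0.10), Cd79a (-0.11), Cd79b (0.18), Ighm (-0.01) and Igha (-0.08) did not pass.

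As a per-array score, Pax5-activated genes averaged 8.11 ± 0.05 log2 units with wild type (SD, n = 3), 7.91 ± 0.21 with G183S (n = 4) and 7.59 ± 0.02 with empty vector (n = 3). The difference of -0.20 between G183S and wild type was not distinguishable from 0 (two-sided exact permutation p = 0.171, adjusted over 2 lists 0.343; the 35 splits allow a smallest p of 0.0286). Without G183S replicate 3 it was -0.11. Pax5-repressed genes averaged 8.38 ± 0.19, 8.46 ± 0.07 and 8.43 ± 0.05, a difference of 0.08 between G183S and wild type (exact permutation p = 0.571, adjusted 0.571). Without wild-type replicate 1 that difference was -0.03.

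The size of the response to G183S was set against that to wild type on genes chosen with 1 wild-type and 1 empty-vector array held out. For genes that rose, the median response to G183S was 0.566 ± 0.200 times that to wild type (SD over the 4 of 9 combinations with at least 5 genes; range 0.365 to 0.839). For genes that fell it was 1.06 ± 0.348 over 2 combinations (0.814 and 1.31). Among rising genes of the 4 combinations the response to G183S was the smaller in 5 of 9, 7 of 13, 6 of 9 and 4 of 8 genes. All but the last of these used empty-vector replicate 1 as the baseline. The ratio for rising genes was 0.237 without wild-type replicate 1 and 0.363 without wild-type replicate 2. Without G183S replicate 1 it was 0.502 ± 0.083 (SD over all 9 combinations, with 19 to 126 genes each). It was 0.867 without G183S replicate 3 and 0.899 with dim probe sets left out. The ratio for falling genes was 2.10 without wild-type replicate 2, 0.682 without G183S replicate 1 and 1.87 without G183S replicate 2. Too few genes were left for a ratio without any empty-vector array in either direction, or for falling genes without wild-type replicate 1 or G183S replicate 4. The combinations share arrays and are not independent, and no test was made on the ratio.

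Both constructs shared 19 genes that rose and 37 that fell, and no gene passed in opposite directions. The 19 include Pax5 itself, the gene introduced, which is not a response to the constructs. The shared higher genes included Cd36, Plxnc1, St3gal6, Bin1, Irf8, Fcgr2b, Ms4a1, H2-Ob, H2-Eb2 and Fhod3, and the shared lower genes Pecam1, Slc16a5, Gp9, Tspan14 and Cd3g. Independent lists would share 0.177 and 0.417 genes; the part of these counts that comes from the shared controls was not estimated. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.698, against 0.535 in 50 simulations of unchanged groups with shared controls. The covariance was 0.0452 against 0.0125, a difference of 0.0327. The 3 controls cannot be split with at least 2 in each part, so the part that comes from sharing them was not measured directly. The simulations gave every array the spread pooled over the groups. Empty-vector arrays tended to differ less among themselves, with an SD over genes of 0.149 to 0.214 between 2 arrays. That SD was 0.254 to 0.368 for wild-type and 0.168 to 0.384 for G183S pairs. The simulated values may therefore overstate what shared controls contribute. The count of shared higher genes was 33, 6 and 5 without empty-vector replicates 1, 2 and 3, 12 without wild-type replicate 2, and 43, 7, 52 and 6 without G183S replicates 1 to 4; that of shared lower genes was 4 and 0 without empty-vector replicates 2 and 3, and 85, 14, 60 and 18 without G183S replicates 1 to 4.

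**Figure D4:**
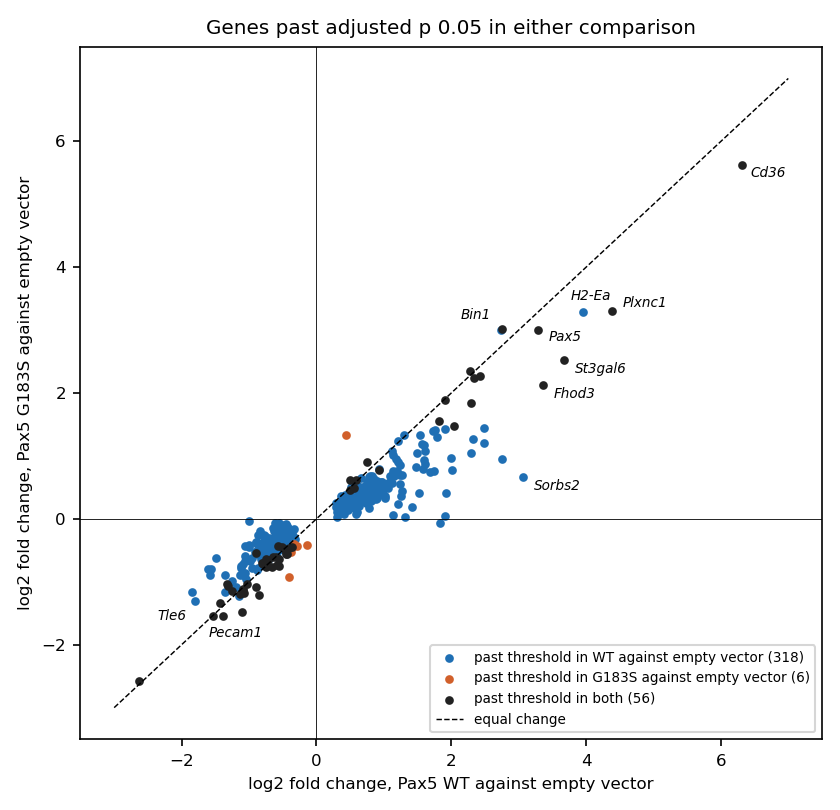
Log2 fold change against empty vector with G183S (y axis) and with wild-type Pax5 (x axis) for genes past the threshold with wild type only (318), with G183S only (6) or with both (56); each point is 1 gene and the dashed line marks equal change. Both axes share the empty-vector arrays, and the genes past the threshold with both include Pax5 itself. Cd36, Plxnc1, St3gal6 and Fhod3 lie below the line and Bin1 lies near it.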

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

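Chosen only after the result was seen were the tests of a single wrong label, shared handling, array quality and the Pax5 level, the tests of selection and of Pax5 transcript on rising genes alone, and the choice to look at G183S replicate 1; the exchange test was framed after correlations between the arrays' deviations had been seen, but before its own result.

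Plxnc1 stood out in the G183S group because G183S replicate 3 read 7.43 log2 units and the other 3 arrays 9.50 to 9.54. The NF-kB list score stood out because G183S replicate 1 had 8.06 and the others 8.59 to 8.63. These were 2 of 78 genes and lists examined for an array far from the rest of the G183S group, where chance gives about 1 in 20. Over all genes 1487 (7.46%) had such an array, which was G183S replicate 1 in 878, replicate 2 in 120, replicate 3 in 327 and replicate 4 in 162.

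For wild type against empty vector, 1 of the 10 splits of the 6 arrays (the real one, 374 genes; highest other 1) gave as many calls, and 10 splits are too few for a share under 0.05. For G183S against empty vector, 2 of 35 splits gave at least the real 62 genes, the highest other being 92 with G183S replicate 1 placed among the empty-vector arrays, so chance is not excluded for that count. For G183S against wild type the real count was 0, which all 35 splits reach whatever the data, so that share carries no information. The highest other split gave 3497, with wild-type replicates 1 and 2 and G183S replicate 1 against the rest. The next gave 2302, with G183S replicate 1 moved to the wild-type group. Both point to a structure of the samples other than the groups. Without G183S replicate 1 the real split gave 1113 genes and the highest other 0, 1 of 10 splits, again too few.

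The first pattern is that G183S replicate 1 lay with the wild-type arrays: without it, 1113 genes separated G183S from wild type. Array quality argues little for it, as its interquartile range of relative log expression, 0.160, lay within the 0.132 to 0.207 of the other arrays. Markers of other cells decided nothing. List medians differed by at most 0.0701 from the other G183S arrays, but members went both ways (Cd5 -0.25, Spi1 -0.07, Cebpb -0.50, Ly6g 1.28, Tfrc 1.05, Itga2b -1.04, Epcam 0.76, Cdh5 0.63). The sort for green fluorescence and IgM may have removed such cells, but Ighm read low in all arrays and the purity of the sort was not examined. A single wrong label may account for it, since 93.9% of the 1113 genes placed the array nearer to wild type. The 68 genes (6.11%) that did not say little against it by their share alone. Wild-type replicates 1 and 2, held out and placed in a like way, lay on their own side for 91.9% and 85.1% of genes. Wild-type replicate 3 did so for 36%. Siglecg (7.81), St3gal6 (10.11) and Nckap1 (9.86), singled out after their values were seen, lay nearer to the other G183S arrays. An exchange with wild-type replicate 3 stays open, because in a fit without both arrays 3.59% of 3068 genes had each on the side of its own label, between the bounds set for and against it, and 57.0% had each on the other side. Shared handling of wild-type replicates 1 and 2 and G183S replicate 1 (3497 genes by that split) and a biological difference between G183S cultures cannot be told apart from these, as the labels name no batch.

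The second pattern is the smaller median rise with G183S, 0.566 times that with wild type over 4 combinations, or 0.674 over 9 with no minimum. Selection on the wild-type arrays stays open as a cause. The test framed before its own result was seen used 65 genes chosen on all Pax5 arrays together, 40 that rose and 25 that fell. Their ratio was 0.783, but 0.984 without wild-type replicate 1, above the bound of 0.95. The 40 that rose, examined alone only afterwards, had a ratio of 0.739. It stayed under the bound without single Pax5 arrays (0.669 to 0.823). Those fits share most of their arrays, so their SD of 0.0494 does not measure the spread between cultures. Less Pax5 transcript in the G183S arrays may account for it and stays open: in the 4 pairs in which the G183S array had at least as much Pax5, the median difference of the rising genes was -0.143 to -0.00253, below 0 but not in each pair by more than the SD over pairs (0.0653), and that of all 65 genes, signed by direction, was 0.05 to 0.102. Those pairs share arrays, G183S replicates 1 and 2 against wild-type replicates 2 and 3, and 2 of them use G183S replicate 1. A difference between the mutant and wild-type proteins stays open too.

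The third pattern is that the response differed between arrays with the level of Pax5. The median response of the 65 genes was 1.87, 1.39 and 1.45 log2 units in the wild-type arrays and 1.36, 1.55, 0.91 and 1.31 in the G183S arrays. It may follow the Pax5 level, with Pearson r = 0.973 over the 7 arrays (exact permutation p = 0.00258, adjusted over 2 measures 0.00516) and Spearman rho = 0.857 (exact permutation p = 0.0238). Without wild-type replicate 1 and G183S replicate 3, the arrays farthest from the median level, r was 0.746 over 5 arrays (exact permutation p = 0.158), still above the bound of 0.5 set for it. It was noticed and tested on the same data, and the groups are mixed in it.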

How the results depend on the processing

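Chosen only after the data were seen were the fit without G183S replicate 1 and wild-type replicate 3 together, the selection on all Pax5 arrays and the ratio with no minimum number of genes; the cause of each change was not tested unless given. Pax5 kept its direction and side of the threshold in every setting in which it was examined. It was not examined with the mean of probe sets, all probe sets, no moderation or the added fit without both arrays. Without single arrays its log2 differences were 3.09 to 3.40 (wild type against empty vector), 2.87 to 3.20 (G183S against empty vector) and -0.42 to -0.09 (G183S against wild type).

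Counts below are for wild type against empty vector, G183S against empty vector and G183S against wild type, reported as 374, 62 and 0. Without single arrays they were 6 to 1033, 8 to 295 and 0 to 1113. Array weights gave 2576, 1449 and 2752 (weight 0.335 for G183S replicate 1, 3.48 for wild-type replicate 2), no moderation 4, 6 and 1, and the added fit without both arrays 2016, 883 and 3068. A fold minimum gave 107 and 29. For wild type, a fit of the groups compared alone gave 587 and all probe sets 189. Dim-probe filtering, normalization, centring, trended moderation and the mean of probe sets stayed within 1.5 times.

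With the replicate number as a block the counts were 228, 10 and 2. The numbers did not pair the arrays as a whole: deviations of same-numbered arrays correlated between -0.162 and 0.507, and 4 of 10 arrays correlated best with their own number. These 4 were replicates 1 and 3 of wild type and G183S (r = 0.507 and 0.455). Wild-type replicate 3 with G183S replicate 1 gave -0.581. An effect shared by number is therefore not excluded for those 4 arrays. With the block, B-cell receptor genes in G183S against empty vector (adjusted p = 0.0604) and endoplasmic reticulum stress (0.0710) and stromal (0.141) genes in G183S against wild type no longer passed; it left 6 higher and 4 lower genes for G183S against empty vector.

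Lists past the threshold, reported as 6, 7 and 7, were 0, 0 and 0 with an estimated correlation. Directional fry gave 4 for G183S against empty vector and 0 for G183S against wild type, where mixed fry gave 1. In the added fit without both arrays, Pax5-activated (adjusted p = 0.0503) and B-cell receptor genes (0.175) in G183S against empty vector, and B-cell receptor, stress (0.108 each) and stromal genes (0.266) in G183S against wild type, did not pass. Without single arrays they were 6 to 7, 6 to 9 and 3 to 8. Cholesterol genes turned from higher to lower with wild type without wild-type replicate 1 (adjusted p = 0.0429; without single arrays 0.0429 to 0.992). Of all list results past the threshold 294 were the same and 86 weaker; of the others 734 were the same, 37 stronger and 45 changed sign while not past it.

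The response ratio was 0.899 for rising genes with dim probe sets left out, and 0.237 to 0.867 (rising) and 0.682 to 2.10 (falling) without single arrays. Other settings gave 0.577 to 0.757 (rising) and 0.882 to 1.34 (falling). Shared calls were 5 to 52 higher and 0 to 85 lower without single arrays. List scores differed by -0.28 to -0.11 (Pax5-activated) and -0.0276 to 0.150 (Pax5-repressed).

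Apart from Pax5, of 64 named-gene results past the threshold, 6 passed in every setting: Fcgr2b and St3gal6 against empty vector with both constructs, and Gp9 and H2-Ob with G183S. Over settings 928 were the same and 350 weaker; of those not past it 4055 were the same, 289 stronger and 24 changed sign. Background signal was not used here, so what it limits at low levels is not given.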

Other observations

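Looking at the arrays without G183S replicate 1 was chosen after its position had been seen. The values here come from leaving that array out and describe 3 G183S arrays against 3 wild-type arrays. Leaving out the G183S array that lay with wild type favours more calls, so the adjusted p here are descriptive and give no separate support. Wild-type replicate 3, when held out, had only 36% of genes on its own side, so the contrast is not cleanly one of construct.

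Among the 1113 genes limma then called, G183S replicates 2 to 4 were higher than wild type for Lrrc8e, a subunit of volume-regulated anion channels (log2 difference 2.98, adjusted p = 0.0139), Acod1, which makes itaconate (1.81), Icam1 (1.59, adjusted p = 0.0407), Nckap1 (1.69) and Adgre1, the macrophage marker F4/80 (1.57). They were lower for Sorbs2 (-2.54, adjusted p = 0.0490), Fcrla, an Fc receptor-like gene of B cells (-1.78, adjusted p = 0.0182), Tnfrsf17 (-1.72, adjusted p = 0.0413), the signalling receptor gene Slamf6 (-1.70), the interleukin-5 receptor gene Il5ra (-1.63) and Fhod3 (-1.49). Empty-vector means lay between wild type and these G183S arrays for each of the higher genes named. They were 8.72 for Lrrc8e, 10.88 for Icam1 and 6.77 for Adgre1, against G183S means of 9.85, 11.68 and 7.39. These differences therefore combine lower wild-type and higher G183S means. For the lower genes the G183S mean lay nearer to empty vector than the wild-type mean did, except for Tnfrsf17. Its empty-vector mean, 11.07, lay above both. In G183S replicate 1 the levels of Lrrc8e, Icam1, Fcrla and Tnfrsf17 were 6.56, 10.17, 10.19 and 10.25 log2 units, against wild-type means of 6.87, 10.08, 10.71 and 10.29, whereas Pxdc1 (8.03), Rassf6 (5.25) and Hsd17b13 (6.51) matched the other G183S arrays more closely.

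In the same fit p53 response genes had 8 of 17 higher (camera adjusted p = 1.78e-04; adjusted p = 0.420 with an estimated correlation) and NF-kB targets 4 of 17 higher (camera adjusted p = 3.81e-04; adjusted p = 0.541 with an estimated correlation). The NF-kB list mean relative to empty vector was -0.49, 0.06 and 0.43 in the wild-type arrays and 0.52, 0.49 and 0.53 in G183S replicates 2 to 4, a difference of 0.51, or 0.27 without wild-type replicate 1. Plasma-cell genes had 4 of 19 lower (camera adjusted p = 2.20e-05; adjusted p = 0.420 with an estimated correlation) and cell-cycle genes 6 of 25 lower (camera adjusted p = 1.78e-04; adjusted p = 0.548 with an estimated correlation), the latter with a list mean difference of -0.41, or -0.27 without G183S replicate 3. Cholesterol synthesis genes were shifted downward with 0 of 16 called by limma (camera adjusted p = 0.00496; adjusted p = 0.548 with an estimated correlation). Their list mean was 0.49, 0.01 and -0.25 in the wild-type arrays and -0.31, -0.27 and -0.13 in G183S replicates 2 to 4, a difference of -0.33, or -0.12 without wild-type replicate 1 and -0.49 without wild-type replicate 3. Glycolysis (camera adjusted p = 0.0237) and B-cell receptor genes (0.0251) also passed as lower and stress genes (0.0251) as higher. With an estimated correlation their adjusted p was 0.490, 0.420 and 0.420. Myeloid markers, which include Adgre1, had 2 of 19 higher and did not pass as a list (camera adjusted p = 0.171).

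When each other array was left out of the fit in turn and then placed by the genes that separated the remaining ones, the share of genes on the side of its own label was 91.9% for wild-type replicate 1, 85.1% for replicate 2 and 36% for replicate 3, and 93.1%, 86.7% and 92.3% for G183S replicates 2, 3 and 4. All of these fits left out G183S replicate 1 as well.

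Ighm lay at 6.17 to 6.34 log2 units and Cd79a at a mean of 4.76 to 5.05 across groups, although the cells had been sorted for IgM; other probe sets of Ighm gave log2 differences of -0.02 and -0.07 with wild-type Pax5.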
